A study of Mus musculus with 16 samples.

How the data were processed

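Gene expression was measured in H295R tumours grown in SCID mice, which lack functional T and B cells. Per the labels, the animals received corn oil (control), mitotane, 9-cis retinoic acid (9-cisRA) or both agents (combined) by mouth for 28 days. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent 4x44K arrays. GEO lists the mouse as the organism, whereas the array design named in the file headers is a human one and H295R is a human line. The labels give 4 arrays per group on 4 slides, each slide with 1 array of each group. The scanner output of 15 arrays was used for the tests, so the combined group had n = 3 and the other groups n = 4. Combined replicate 3 was analysed only through the series value table. Replicate numbers follow accession order, and each number is also the slide. The labels do not state that every array came from a separate mouse, so p-values measure the spread between these samples, part of which may be technical.

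The scanner files hold 1 intensity per spot, deposited by the authors as Agilent Feature Extraction output. The processed signal is background-subtracted and spatially detrended within the array, per the file headers, with no scaling between arrays. The extraction software was Agilent Feature Extraction version 11.0.1 per the submitters' processing notes and 11.0.1.1 per the file headers. The series value table holds log2 values deposited by the authors, and its processing is not given in the sources used here. Set against the scanner files, the columns of the 15 arrays that have one were close to the log2 signal scaled to a 75th percentile. They were then centred on the probe's median over 16 arrays. Differences between arrays correlated with the scanner values at r = 1.00 after rounding over 18259 probes, and the largest median absolute difference was 0.068. Scaling of a whole array leaves r unchanged, so the 0.068 alone bears on the percentile. The column median over tested transcripts was -0.42 for control replicate 4 and between -0.03 and 0.06 for the other 15 arrays. The exact set of spots behind the authors' percentile stays unknown. The table lists 34183 probes with control probes included, of which 34127 matched a probe of the scanner files.

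From the scanner files, log2 of the processed signal was taken minus the array's 75th percentile over 43118 non-control spots. Spots marked as non-uniform or population outliers were left out, and the spots of a probe were averaged. A probe with all of its spots so marked on an array kept its value there, which concerned 86 values among the transcripts tested. Saturated spots were kept. One probe, that with the highest mean, stood for each of 29094 identifiers, of which 4369 had several probes. A transcript was tested when its probe was well above background on every array of at least 1 group, which left 20216 transcripts, or 69.5%. All 4 groups entered one linear model in limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that they shared one estimate of the spread. P-values are two-sided, were adjusted by the Benjamini-Hochberg method within a comparison, and were held to an adjusted p of 0.05. Files were read with the data.table package (version 1.17.8), and plots were drawn with matplotlib 3.10.9.

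The comparisons were mitotane, 9-cisRA and combined against control, combined against each single agent, and the interaction (combined minus mitotane minus 9-cisRA plus control). The fits were tested on simulated data with 100 transcripts changed 2-fold and 100 changed 4-fold among 20216, drawn with the spread measured on each array. The fold of a transcript that no array of a group measured well above background is given as a bound. It sets the bright group's mean over all its replicates against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

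The files do not pair the probes with gene names, and the accessions are human. The reference table at hand was a mouse one (GRCm38.p6), and 0 of the 29094 identifiers matched it, so no gene is named. The 30 gene and cell type lists fixed before the data were examined, with 510 genes, matched 0 identifiers and were not tested. The rule fixed for named genes took those with adjusted p under 0.05 and the largest change, then those with the smallest unadjusted p. It passed over rows whose name is an accession or a probe identifier. Every row is either, so the rule named none. In its place the 2 identifiers per direction with the smallest unadjusted p are given for each comparison, a choice made after the data were seen. Identifiers were also grouped by kind of accession, likewise afterwards, and tested with limma's camera at a preset correlation of 0.01. The kind called other accessions takes in any probe names. The 5 kinds together hold every transcript tested, and camera sets each kind against the rest. Calls of several kinds in a comparison are therefore not separate results.

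Alternatives chosen beforehand were normexp background correction (offset 50) with quantile normalisation, quantile normalisation alone, no filter and a stricter filter on dim probes, the slide as a block, only the groups compared, array weights, the mean of all probes, a trended and robust variance, a 1.5-fold minimum, the value table with 16 or 15 arrays, and each array left out. Normexp used the median spot signal, since the scanner files used here hold no mean signal. Omitting control replicate 4 together with combined replicate 4, and omitting control replicate 4 or both from the value table, were added after the data were seen, as was the test by kind of accession without control replicate 4. The number of arrays limits the precision, and the median standard error of a log2 change was 0.22 for each single agent against control and 0.23 for combined against control.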

Results

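The study followed tumours of H295R, a hormone-producing human adrenocortical carcinoma line, in SCID mice after 28 days of oral treatment. Mitotane is an adrenolytic drug given for adrenocortical carcinoma, and 9-cisRA is a retinoid that activates the nuclear receptors RAR and RXR. The design text gives 4 groups, namely control, mitotane, 9-cisRA and combined. The question was how each agent and their combination altered gene expression in the tumour. Scanner data of 15 arrays were tested, 4 each of control, mitotane and 9-cisRA and 3 of combined treatment.

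The arrays read 34127 probes with 29094 identifiers, and 20216 transcripts passed the filter on dim probes. The tested share was 76.6% of 19971 RefSeq mRNA identifiers, 56.9% of 1832 RefSeq non-coding RNAs and 51.1% of 2622 Ensembl transcripts. Of the tested transcripts, 15744 were well above background on every array. The 75th percentile of the signal was an intensity of 224.2 on control replicate 4 and between 551.5 and 1061 on the other 14 arrays. Control replicate 4 had a median Pearson r of 0.874 with the other arrays, across transcripts, which are not independent replicates. The median r of each of the other 14 arrays lay between 0.977 and 0.99. Combined replicate 4 had the lowest share of probes well above background, 57.9%, followed by control replicate 4 with 61.6%, against 69.4% to 75.9% on the remaining arrays. The first principal component held 58.5% of the variance and set control replicate 4 apart. The second held 9.7% and set combined replicate 4 apart, at -64.7 against -16.9 to 20.8 on the other arrays. The 9-cisRA array lay at position 4 of all 4 slides, so array position and 9-cisRA cannot be told apart. Controls lay at position 3, except control replicate 4 at position 2.

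**Figure D1:**
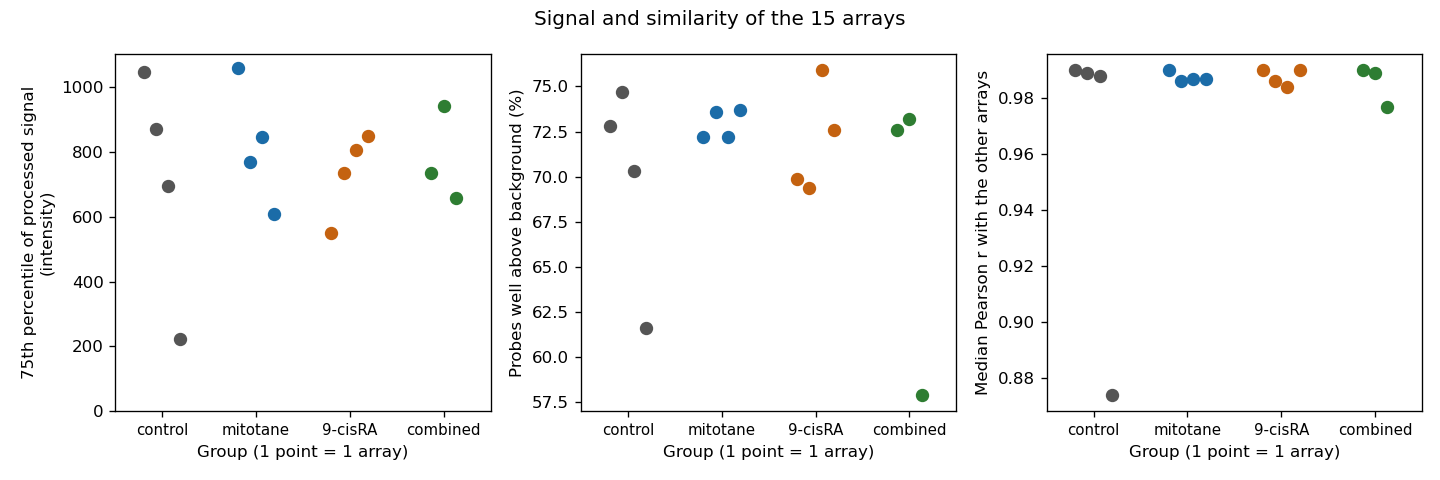
Each point is 1 of the 15 arrays, by treatment group: left, the 75th percentile of the processed signal (intensity); middle, the share of probes well above background (%); right, the median Pearson r with the other arrays. Control replicate 4 sits lowest for intensity, at 224.2, and for r, at 0.874, while combined replicate 4 has the lowest share of probes, at 57.9%.

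Mitotane was compared with corn oil to read its effect as a single agent. The transcript with the smallest unadjusted p was ENST00000318245, at a log2 signal relative to the 75th percentile of -5.47 ± 0.59 (SD, n = 4) in control and -2.05 ± 0.65 (n = 4) under mitotane. Its log2 change was 3.43 ± 0.60 (SE), a 10.7-fold difference, and 3 of the 4 control arrays measured it above background. NM_152288 was 2.24-fold higher, with a log2 change of 1.16 ± 0.24, which was 0.59 with normexp and quantile normalisation (normexp below), and 3 of the 4 control arrays measured it above background. Among lower transcripts, NM_183419 had a log2 change of -1.26 ± 0.34 and ENST00000334082 one of -0.87 ± 0.23, or -0.20 with normexp. ENST00000334082 was measured above background on 3 of the 4 control arrays. None of the 4 passed the test (adjusted p = 0.713, limma).

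With limma, 0 of 20216 transcripts passed for mitotane against control, and 1221 (6.04%) had an unadjusted p under 0.05, with 1011 expected by chance. Of these, 1035 were higher and 186 lower under mitotane. Without control replicate 4 the balance was 1085 higher and 467 lower, and in the value table without that array 782 higher and 628 lower. The signals of both groups did not overlap for 858 transcripts (4.24%), where chance gives 2.86% on average. Transcripts vary together on an array, so such a share can lie far from its average by chance. Non-overlap was not counted over other splits of the arrays in any comparison, so these shares do not show an effect. No kind of accession passed camera for mitotane. Without control replicate 4 all 5 kinds passed with the preset correlation and 1 with an estimated one, the RefSeq mRNAs (adjusted p = 0.00707), which tested lower than the rest although their median change was 0.06. Each kind is set against the others, so these are not 5 separate results. With array weights, an alternative limma fit, 3 transcripts passed, ENST00000318245 among them. The log2 change of ENST00000318245 was 1.33 after normexp correction and quantile normalisation, and the 1221 became 2074 without control replicate 1, 688 without mitotane replicate 2 and 575 without mitotane replicate 3.

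9-cisRA was compared with corn oil in the same way. NM_001352 was 1.68-fold higher, at 0.25 ± 0.33 (SD, n = 4) in control and 1.00 ± 0.18 (n = 4) under 9-cisRA, a log2 change of 0.75 ± 0.17 (SE), which was 0.31 with array weights. NM_183373 had a log2 change of 1.19 ± 0.28, which was 0.24 with normexp and quantile normalisation, and was measured above background on 4 of 4 arrays under 9-cisRA and 2 of 4 control arrays. ENST00000334082, also lower under mitotane against the same control arrays, had a log2 change of -1.08 ± 0.23, or -0.28 with normexp. XR_108461 was not well above background on any 9-cisRA array, while 3 of 4 control arrays measured it. With the main processing the bound put it at least 2.08-fold lower than in control. Its measured means were -4.97 in control and -6.62 under 9-cisRA. The change was -0.20 with normexp, so the bound does not hold there. The groups overlapped, with 9-cisRA replicate 1 at -5.76 and control replicate 2 at -5.89. None of these 4 passed (adjusted p = 0.744, limma).

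For 9-cisRA, 0 transcripts passed in limma and 710 (3.51%) had an unadjusted p under 0.05, of which 437 were higher and 273 lower. That balance turned to 432 higher and 446 lower without control replicate 4, 400 and 473 in the value table without that array, 257 and 338 without 9-cisRA replicate 1, and 354 and 417 with no filter on dim probes. With normexp and quantile normalisation it was 622 higher and 187 lower. Array weights gave 4 calls. Non-overlap was seen for 484 transcripts (2.39%, with 2.86% by chance). By kind of accession, the median log2 change was 0.08 over 15299 RefSeq mRNAs and -0.15 over 1341 Ensembl transcripts, and camera with its preset correlation gave adjusted p = 3.9e-08 and adjusted p = 1.77e-06. With an estimated correlation neither passed, at adjusted p = 0.0571 and adjusted p = 0.14. The median was -0.18 over 2271 other accessions and -0.14 over 262 predicted RefSeq transcripts, and their preset calls (adjusted p = 2.79e-08 and adjusted p = 0.00436) were likewise lost with an estimated correlation (adjusted p = 0.14 and adjusted p = 0.307). Control replicate 4 itself deviated from the other controls the opposite way, with medians of -0.45 for RefSeq mRNAs, 0.20 for Ensembl transcripts, 0.49 for other accessions and 0.35 for predicted transcripts. Without that array these 4 median changes were 0.02, -0.03, 0.004 and 0.04, and 0 of 5 kinds passed with either correlation. The kinds also differed in signal. Of the tested RefSeq mRNAs 12653 were well above background on every array, and of the tested Ensembl transcripts 763. Kind of accession and signal level were not told apart. The 710 became 1908 without control replicate 1 and 1131 without control replicate 2.

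Combined treatment was compared with corn oil to read the effect of both agents. NM_152612 was 1.95-fold higher, at -3.25 ± 0.05 (SD, n = 4) in control and -2.29 ± 0.24 (n = 3) under combined treatment, a log2 change of 0.96 ± 0.16 (SE), or 0.51 with normexp. NM_025049 was 1.92-fold higher, with means of 0.86 ± 0.15 (SD, n = 4) and 1.80 ± 0.20 (n = 3). ENST00000334082, against the same control arrays again, had a log2 change of -1.21 ± 0.25, or -0.31 with normexp, and was above background on 2 of 3 combined arrays. NM_003131 had a log2 change of -1.37 ± 0.34, which was -0.94 without control replicate 4 and -0.50 with normexp, and it too was above background on 2 of 3 combined arrays. None of the 4 passed (adjusted p = 0.213, limma). The mean of NM_152612 was -3.08 ± 0.13 (n = 4) under mitotane and -3.35 ± 0.22 (n = 4) under 9-cisRA.

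**Figure D2:**
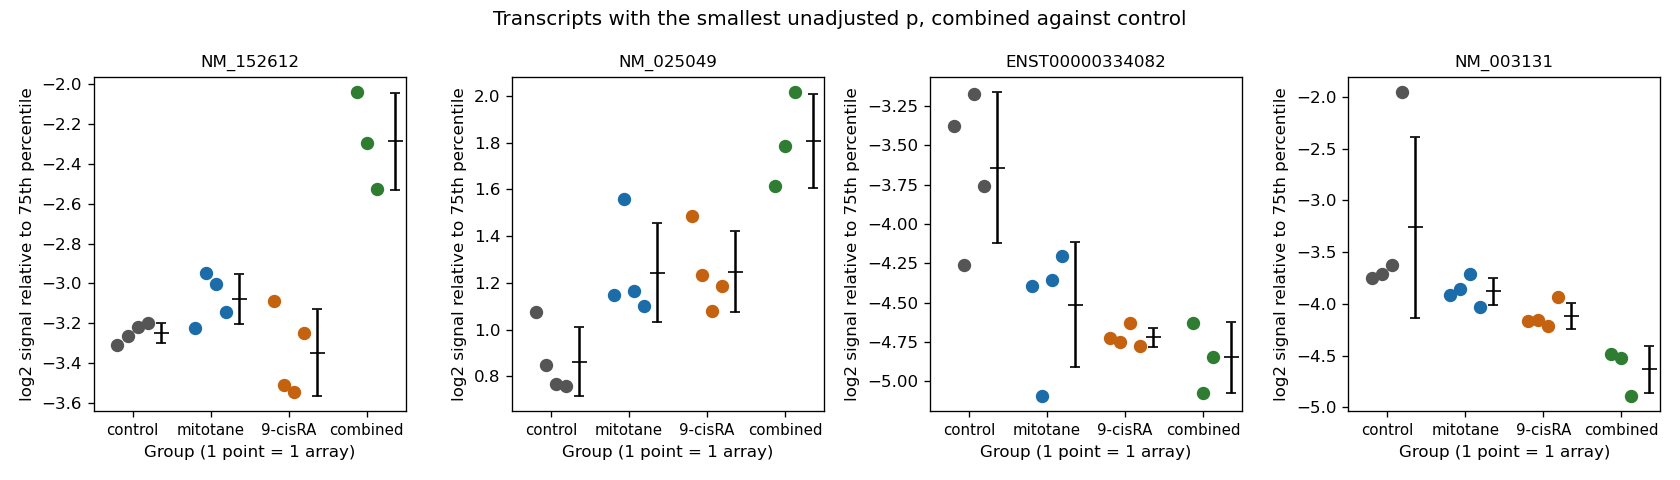
Each panel gives 1 transcript by its identifier, with the log2 signal relative to the array's 75th percentile on the vertical axis and the 4 groups on the horizontal axis. Points are arrays, and the bar beside them is the mean ± SD (n = 4, or 3 for combined). The combined arrays of NM_152612 lie above all other arrays, with a mean of -2.29.

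For combined against control, 0 transcripts passed in limma, while 2787 (13.8%) had an unadjusted p under 0.05 against 1011 by chance. Of these, 2340 were higher and 447 lower. Without control replicate 4 there were 2659 higher and 1037 lower, and in the value table without that array 2865 higher and 1694 lower. The signals did not overlap for 3067 transcripts (15.2%), where chance gives 5.71% on average, a share not checked over other splits. Array weights gave 5788 calls, with a weight of 8.81 on control replicate 2 and 0.04 on control replicate 4. The median change of the 1043 RefSeq non-coding RNAs was 0.18, with adjusted p = 0.0346 in camera at the preset correlation and adjusted p = 0.748 with an estimated correlation. Without control replicate 4, 3 of the 5 kinds passed with the preset correlation and 1, the RefSeq mRNAs, with an estimated one (adjusted p = 0.0342). Without combined replicate 4 the 2787 became 1612, and with only these groups in the fit they became 1312.

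**Figure D3:**
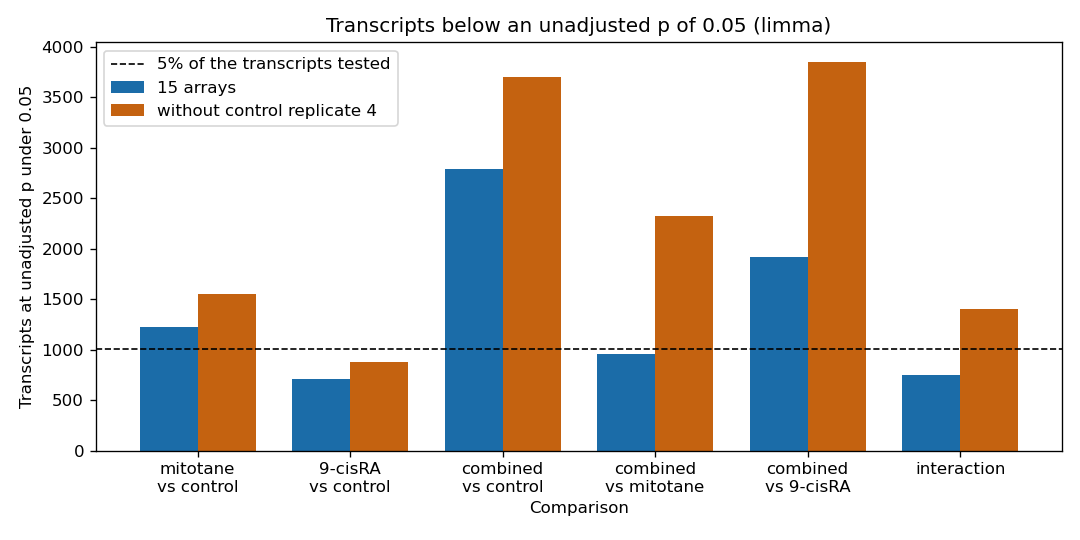
Bars count the transcripts with an unadjusted p under 0.05 (limma) for each comparison, with all 15 arrays (blue) and without control replicate 4 (orange), and the dashed line marks the 1011 expected by chance. Combined against control reaches 2787 with 15 arrays and 3696 without control replicate 4, and no comparison has a transcript past the adjusted threshold in either fit.

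Combined treatment was set against mitotane to read what 9-cisRA added. NM_001039651 was 2.41-fold higher, at -1.06 ± 0.38 (SD, n = 4) under mitotane and 0.21 ± 0.26 (n = 3) under combined treatment. NM_000444 had a log2 change of 0.83 ± 0.16 (SE), or 0.44 with normexp. NM_001042576 had a log2 change of -0.69 ± 0.13 and NM_021934 one of -0.62 ± 0.12. None of the 4 passed (adjusted p = 0.66, limma). In total 0 transcripts passed and 960 (4.75%) had an unadjusted p under 0.05, with 596 higher and 364 lower; array weights gave 103 calls. Non-overlap was seen for 2232 transcripts (11%, with 5.71% by chance). RefSeq non-coding RNAs had a median change of 0.06 (camera, adjusted p = 0.0237 with the preset and adjusted p = 0.667 with an estimated correlation). The 960 became 2323 without control replicate 4, which enters this comparison through the shared spread alone, and 590 without combined replicate 4.

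Combined treatment was set against 9-cisRA to read what mitotane added. NM_152612 was 2.09-fold higher (adjusted p = 0.163, limma), with a log2 change of 1.06 ± 0.16 (SE), or 0.50 with normexp. NR_028351 had a log2 change of 1.41 ± 0.27 (0.45 with normexp), NM_013442 one of -0.75 ± 0.16 and NM_183373 one of -1.38 ± 0.30 (-0.27 with normexp), each with adjusted p = 0.28 in limma. NM_183373 was above background on 1 of 3 combined arrays. Here 0 transcripts passed and 1915 (9.47%) had an unadjusted p under 0.05, of which 1503 were higher and 412 lower, or 997 and 519 after quantile normalisation and 2758 and 1608 in the value table without control replicate 4. Array weights gave 2003 calls. The median log2 change was 0.20 over 1043 RefSeq non-coding RNAs (camera, adjusted p = 2.03e-05 with the preset and adjusted p = 0.114 with an estimated correlation). All 5 kinds of accession passed camera with the preset correlation here and none with an estimated one, or RefSeq mRNAs alone without control replicate 4 (adjusted p = 0.00555). RefSeq mRNAs tested lower than the rest, although their median change was 0.04. As each kind is set against the others, these are not 5 separate results. Non-overlap was seen for 3306 transcripts (16.4%, with 5.71% by chance). The 1915 became 3850 without control replicate 4 and 1268 without 9-cisRA replicate 2.

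The interaction asked whether the combined effect departed from the sum of the single effects on the log2 scale. The interaction term of NM_006898 was 0.86 ± 0.19 (SE) and that of NM_152612 was 0.89 ± 0.21, or 0.50 and 0.41 with normexp. It was -2.45 ± 0.49, or -0.83 with normexp, for NM_002110, which 2 of 3 combined arrays measured above background. NM_183373 had the smallest unadjusted p among negative terms, but 1 of 3 combined and 2 of 4 control arrays measured it above background, and its term ran from -2.95 to -0.34 over the alternatives. The mean of NM_002110 was -4.20 ± 0.61 (SD, n = 4) in control, -2.84 ± 0.53 (n = 4) under mitotane, -3.11 ± 0.51 (n = 4) under 9-cisRA and -4.19 ± 0.14 (n = 3) under combined treatment. None passed (adjusted p = 0.965, limma). In all, 0 transcripts passed, also with array weights, and 751 (3.71%) had an unadjusted p under 0.05. Without control replicate 4 the 751 became 1404, and without mitotane replicate 2 they became 479.

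The log2 changes of mitotane and 9-cisRA, both against the same control arrays, correlated with Pearson r = 0.742 across 20216 transcripts, which are not independent replicates. Simulated groups with no effect against the same controls gave r = 0.82. The covariance was 0.102, and 0.113 in the simulation. Without control replicate 4, r was 0.43 against 0.466 in the simulation, and the covariance was 0.0267 against 0.0217. With the controls split 2 and 2 between both comparisons, r lay between -0.378 and -0.110. In each split control replicate 4, with a spread of 4.12 relative to the other arrays, entered only the mitotane or only the 9-cisRA comparison. The splits were not simulated, so the negative r does not show that the agents act in opposite directions.

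On simulated arrays with the measured spread, the fit called 62% of transcripts changed 2-fold and 87% of those changed 4-fold for mitotane against control. For 9-cisRA against control the shares were 59% and 89%, and for combined against control 51% and 87%. The simulated noise was independent between transcripts, whereas the correlation estimated within a kind of accession was 0.0325 to 0.0826 on the real arrays. The shares may therefore not carry over to the real arrays.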

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

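The rule for arrays far from their group was fixed in advance and covered 72 sets of 4 arrays, of which chance marks about 1 in 20, or 3.6. Most sets were log2 signals of identifiers picked by their small p on these same arrays, so that rate need not hold for them. The combined group, with 3 arrays, was not covered, so combined replicate 4 could not be marked. The check on kinds of accession was chosen after control replicate 4 had been seen to stand apart.

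Control replicate 4 stood apart from the other 3 control arrays in its median r with all arrays (0.874, others 0.988 to 0.99), in the median SD between copies of a probe (0.117 on the log2 scale, others 0.072 to 0.075) and in the number of outlier spots (511, others 281 to 313). Other arrays of its slide were raised in outlier spots and in the SD between copies, combined replicate 4 with 589 and 0.093 and mitotane replicate 4 with 445 and 0.086, while 9-cisRA replicate 4 had 340 and 0.075. Control replicate 4 also stood apart in the log2 signal of NM_183419, at 1.30 against at most 0.05 in the other controls, and of NM_003131, at -1.96 against at most -3.62.

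Control replicate 4 differed from the mean of the other controls by at least 2-fold upward for 23.8% of tested transcripts and downward for 10.8%. Weak labelling would spare bright transcripts. Among the 5054 brightest, however, the SD of its deviation was 1.14, which is 4.94 times the highest of the other controls. This argues against weak labelling as the whole cause. It may be a part, since the spike-in signal minus the 75th percentile was 2.91 on the log2 scale, against -0.15 to 1.68 on the other arrays. A spot or area defect would spread the copies of a probe, but their median SD was 0.076 of the SD of the array's deviations over 999 probes with 10 copies, which argues against a defect as the whole cause; what raised the copies and outlier spots on 3 arrays of this slide was not tested. RNA of other cells or of another sample may be involved: 243 transcripts were well above background on this array alone, below the 451 of 9-cisRA replicate 3, and although a count at or below the highest other array had been set to argue against it, this array is the dimmest (intensity 224.2) and detects fewer transcripts, so the explanation stays open. Its median deviation was -0.45 for RefSeq mRNAs and 0.20 for Ensembl transcripts; RNA quality was not measured and no biological explanation was tested.

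Among the remaining arrays, 9-cisRA replicate 3 had a median SD between copies of 0.077 against 0.075 on each of the other 9-cisRA arrays. This mark rests on the tie of the rounded values at 0.075, and mitotane replicate 2 had 0.077 without being marked. Mitotane replicate 1 had a log2 signal of -2.82 for NM_152288, with the others between -2.06 and -1.94. Mitotane replicate 2 had 1.56 for NM_025049, with the others between 1.1 and 1.17. 9-cisRA replicate 2 had -1.19 for NM_001039651, with the others between -0.45 and -0.34.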

How the results depend on the processing

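Tests of kinds of accession and those that omit control replicate 4 together with combined replicate 4, or control replicate 4 or both from the value table, were chosen after the data were seen. The count of 0 calls held in all 6 comparisons under every alternative except array weights and 3 others. Array weights gave 3 calls for mitotane, 4 for 9-cisRA and 5788 for combined against control, 103 for combined against mitotane and 2003 for combined against 9-cisRA; the 3 were AK127488, ENST00000318245 and NM_002110 and the 4 were ENST00000264899, ENST00000452153, NM_001135920 and NM_022557, singled out after their values were seen. For combined against mitotane, leaving out 1 array gave 0 to 1 calls, the 1 being NM_000316 without mitotane replicate 2. The value table gave 1 without control replicate 4 and 1 without that array and combined replicate 4, NM_176812 both times. The lowest adjusted p ranged over the alternatives from 0.0209 to 0.885 for mitotane, 0.0197 to 0.874 for 9-cisRA, 5.74e-05 to 0.767 for combined against control, 0.00434 to 1 for combined against mitotane, 0.000533 to 0.696 for combined against 9-cisRA and 0.0557 to 0.998 for the interaction. The cause was not tested.

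The number at unadjusted p under 0.05 ranged from 575 to 4462, 303 to 2362, 1312 to 8548, 590 to 3249, 1268 to 5652 and 479 to 2594 in the same order. With the slide as a replicate block, 0 transcripts passed in each comparison. Arrays of different groups on one slide had a median correlation of deviations of 0.01 (7 of 21 pairs above 0.1). On different slides it was -0.02 (18 of 63 pairs), so the number did not visibly pair arrays. The control mean held control replicate 4, so this check cannot exclude a slide effect. None of the 680 alternative values of the 24 identified changes reversed, and 13, all with array weights, passed. The 24 had been picked by the smallest p on these same arrays, so a kept direction was likely beforehand.

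With the controls split, the correlation of mitotane and 9-cisRA changes was reversed, at -0.378, -0.218, -0.110, -0.200, -0.124 and -0.261. Shared controls no longer add to it there, but control replicate 4 weighs on only the mitotane or only the 9-cisRA change. The sign therefore does not show opposite effects. The correlation was 0.487 with array weights and 0.430 to 0.852 with 1 array left out. It was also 0.430 without control replicate 4 and combined replicate 4, and in both value table settings that omit control replicate 4. No combined array enters this correlation, and scaling of a whole array leaves r unchanged. These settings therefore repeat the value without control replicate 4 and are no further check. The median change under 9-cisRA turned from -0.18 to 0.004 for other accessions and from -0.14 to 0.044 for predicted transcripts without control replicate 4, which deviates upward in both. Quantile normalisation moved the median change of all transcripts under mitotane from 0.09 to 0.11, and under 9-cisRA from 0.03 to 0.09. The gene list tests, their alternatives and the interaction with only the groups compared were not run. With normexp, an offset, the median spot signal and quantile normalisation, all changed at once, the 24 identified changes were smaller. Of these, 13 were under 50% and 8 under 33% of their size, down to 12.1% for XR_108461. No other alternative, quantile normalisation alone included, made the change of XR_108461 smaller than this -0.20. The normexp correction, the offset and the median signal were not tested apart.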

Other observations

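The counts over other splits of the arrays at unadjusted p under 0.05 and the pairwise distance tests were chosen after the results were seen, while the tests with array weights and over all transcripts were fixed before their results.

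Combined treatment gave more transcripts at an unadjusted p under 0.05 than either agent against control, yet other groupings of the same arrays gave as many. For combined against control, 6 of 35 splits gave at least the 2787 of the real one, up to 4752, for mitotane 11 of 35 gave at least 1221, up to 3816, and for 9-cisRA 26 of 35 gave at least 710, up to 2145. For combined against mitotane it was 3 of 35 (960, highest other 1371), for combined against 9-cisRA 2 of 35 (1915, highest other 2030), and for the interaction 41 of 100 drawn splits (751, highest other 3604), so chance could not be excluded for any of them. The 4752 set combined replicates 1 and 4 with control replicate 4 against the rest. The 3816 set mitotane replicate 1 with control replicates 1, 2 and 3 against the rest. Both keep part of the real contrast, so they are not unrelated groupings. Splits were not run without control replicate 4, where the real count for combined against control was 3696. The 3 splits that set slides apart gave 546 to 2515 for mitotane, 317 to 1747 for 9-cisRA and 479 to 3764 for combined against control, so the highest lay above the real values, while the slide as a replicate block gave 1078, 732 and 2553. For combined against mitotane they gave 98 to 283 and for combined against 9-cisRA 230 to 563, below the real values. With array weights estimated anew, 3 of 35 splits gave at least the 5788 calls of combined against control, the others being 7115 and 6212. Both others kept the combined arrays together, with control replicate 4 (7115) or control replicate 1 (6212) moved to their side. They hold most of the real contrast, so they are a poor measure of chance, which could not be excluded there either. The estimation of weights stopped early in 7 of the 35 splits, that with 6212 among them, but not in the real split or that with 7115.

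Over all tested transcripts of the 16 arrays in the value table, groups held 20.3% of the squared distances (permutation within slides, p = 0.351), and 30.3% without control replicate 4 (p = 0.00908). Treatment or array position may therefore separate the arrays once control replicate 4 is set aside. This hypothesis was found and tested on the same arrays, and the result with all arrays leaves it open. Slide held 21.1% with all arrays (permutation p = 0.305) and 21.6% without control replicate 4 (p = 0.442), so slide did not part the arrays beyond permuted labels in either set. Array position was not tested apart from treatment. The 9-cisRA arrays lay at position 4 of every slide, and without control replicate 4 every control lay at position 3. Combined arrays lay at positions 1 and 2, so group and position largely coincide in that set. Pairwise, groups held the highest share for combined against 9-cisRA with all 16 arrays (23.9%, exact permutation p = 0.0286, the lowest that 70 arrangements can give, so that 1 pair alone could not get below its 0.143 after adjustment over 5 pairs) and for combined against control without control replicate 4 (31.0%, exact p = 0.0571, adjusted 0.143).

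NM_152612 was higher under combined treatment than in each other group, at a mean of -2.29 against -3.25, -3.08 and -3.35 for control, mitotane and 9-cisRA. Its direction held under the alternatives run for combined against control and against 9-cisRA. As it had been picked by its small p on these arrays, this was likely beforehand. Its change fell from 0.96 to 0.51 and from 1.06 to 0.50 with normexp and quantile normalisation. Combined against mitotane was not run for this transcript under alternatives. With array weights its adjusted p was 5.74e-05 against control and 0.000533 against 9-cisRA, and the lowest otherwise was 0.0523, for combined against 9-cisRA without control replicate 4 and combined replicate 4. Combined replicate 4 lost the signal of 1112 transcripts that the other 14 arrays all measured well above background, and control replicate 4 lost 806, against at most 6 on any other array.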
